A study of Mus musculus with 6 samples.

How the data were processed

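Total RNA of muscle, adipose tissue and liver was extracted with a column kit, amplified, labelled with Cy5 and hybridised to one-colour mouse oligonucleotide arrays, per the labels' protocols. The samples comprised 6 arrays, 1 for each of 2 treatments (MCSE or PBS) in 3 tissues. Groups were taken from the tissue and treatment labels. The authors deposited a table of normalized intensities on a linear scale, with 29922 probes and 6 columns. The submitters' processing notes name limma, without a version or a role. The background correction, the normalization and the genome build were not given in the sources used here. The values themselves showed that the arrays had been brought to a common distribution. Each column had a median log2 intensity of 8.95, and sorted values differed from their median over the 6 arrays by at most 0.038 on the log2 scale. Such scaling assumes that all arrays share 1 distribution of intensities, and it stretches a weak array to the range of the others. No detection calls were used here.

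Probes were named through the platform annotation, which gave 1 gene symbol for 21020 probes and none for 8902, with 0 probes of several symbols. Symbols are those of the annotation and can be old, and list members were matched through synonyms in a RefSeq gene table. The 21020 probes held 16675 symbols, of which 3539 had 2 or more probes. Coordinates are not given, since no build was named.

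Intensities below the 5th percentile (214.2) were raised to it and log2 was taken. Because the medians were equal, the deposited scale was kept. Each gene was represented by its brightest probe, by mean log2 value over the 6 arrays. A gene counted as measured in a tissue when it reached the median of all probes on at least 1 of the 2 arrays, which left 10711 genes for muscle, 13133 for adipose and 11342 for liver. The difference was log2 MCSE minus PBS, and a gene was counted as higher or lower from 2-fold on. With 1 array per group no test of MCSE against PBS was made, and the number of arrays limits the precision. The SD per probe was estimated from the gap between the differences of 2 measured probes of the same gene. It holds probe error and differences between transcripts, and no variation between mice.

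Before the data were examined, 26 pathway lists and 21 cell type marker lists were fixed. The median difference of a list with at least 5 measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes the 2 arrays and is no test of MCSE. An error of the median was drawn from bootstrap samples of the members. The kidney list (32 symbols, 28 on the array) and a heart list (14 symbols, 13 on the array) were added after the data were seen. None of the 28 kidney genes stood on another list (0), and 17 passed the filter on dim probes on the muscle arrays. Genes named in the text followed a rule fixed beforehand. It took, per tissue, the 10 largest differences each way with both arrays at or above the 25th percentile, at most 4 members past 2-fold per pathway list, and a set of genes of insulin action whatever their value. The cell type markers were named for the tissue comparison. Other genes (Tnf, Il1b, Fos, Sos1, Flot1, Eif4ebp1, Gpt1, Atp5a1, Smyd1, the kidney genes, Tnnt2, Myh6 and Myl7) and second probes were named after their values were seen.

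Tissues were compared with limma 3.58.1 in R 4.3.3 on log2 values (lmFit and eBayes, 6 arrays, 2 per tissue), with Benjamini-Hochberg adjustment. The 2 arrays of a tissue came from differently treated mice, so their spread holds any effect of MCSE. The fit had 3 residual degrees of freedom and a prior of 3.2. It was tested on simulated data for muscle and liver over 13862 genes with 200 changed genes. It recovered 25 of 50 genes changed by 1 on the log2 scale and 50 of 50 at each of 2, 3 and 4, with 8 false calls. The simulated noise had an SD of 0.322, below the prior SD of 0.669 in the fit of the real arrays, so these shares do not carry over to them. The list percentile was tested on 100 simulated lists of 20 genes from the 10711 muscle genes. Of the unshifted lists, 5 fell outside the central range, and of lists shifted by 0.5, 100 lay above it. The simulated genes varied independently, whereas members of a real list can vary together, so these shares do not carry over to real lists.

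The alternatives chosen before the data were examined were quantile normalization, centring each difference on its median, removal of a trend with brightness (lowess), the mean over all probes of a gene, no filter or an upper quartile filter on dim probes, 32 added before log2, other thresholds, the mean over list members, treatment as a term of the tissue fit, eBayes with trend, and leaving out each array. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.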

Results

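Gene expression was measured in muscle, adipose tissue and liver of ob/ob mice, a strain that lacks functional leptin and becomes obese and insulin resistant. Mice were fasted for 4 h and received either MCSE, an aqueous extract of bitter melon (Momordica charantia) seeds, or phosphate-buffered saline (PBS) by mouth, 15 min ahead of an intraperitoneal glucose load of 1 g/kg. Tissues were taken 4 h after the glucose. The data comprised 6 one-colour arrays of 29922 probes, 1 for each combination of tissue and treatment, so no difference between MCSE and PBS had a replicate check and none was given a p-value. The labels did not state whether the RNA of several mice was pooled. Differences are given as log2 MCSE minus PBS. As a gauge of technical error, the difference scattered between pairs of probes for the same gene with an SD per probe of 0.519 on the muscle pair, 0.607 on the liver pair and 1.718 on the adipose pair.

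The series title names a search for an insulin receptor-binding protein in this plant, and the question for MCSE was which genes of insulin-responsive tissues differed with it. The first question here was whether each array carried the genes of its labelled tissue. Both muscle arrays did. The genes of fast-twitch fibres had a median log2 intensity of 15.85 on the PBS muscle array and 15.77 on the MCSE muscle array, against at most 9.35 on any other array. Ckm, the muscle creatine kinase, lay at 15.96 and 15.83, and Mylpf, a fast myosin light chain, at 16.01 on both. The 4 other arrays did not separate by their labels. Both liver arrays and the MCSE adipose array carried adipocyte genes, hepatocyte genes and kidney genes together. Lep, the fat-cell hormone gene, lay at 15.04 on the PBS liver array, 15.93 on the MCSE liver array and 16.02 on the MCSE adipose array, and Cidec, a lipid-droplet gene, at 15.56, 15.27 and 15.45. Alb, serum albumin of hepatocytes, lay at 15.79, 15.36 and 15.31 on the same arrays, and Ttr near 14 on all of them. Umod, made in the thick ascending limb of the kidney, lay at 12.5 on the PBS liver array and 14.3 on the MCSE liver and MCSE adipose arrays, but at 8.4 and 9.1 on the muscle arrays. A list of 28 kidney genes, drawn up after these values were seen, had a median of 10.92 on the PBS liver array, 12.40 on the MCSE liver array, 12.46 on the MCSE adipose array and 8.64 on the PBS muscle array. The muscle arrays were not free of genes of other tissues. White adipocyte genes had a median of 12.35 on the PBS muscle array and 12.57 on the MCSE muscle array. On the same 2 arrays Lep lay at 12.98 and 12.94, and Alb at 12.35 and 10.44.

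The array labelled MCSE adipose was nearly the same as the array labelled MCSE liver. Over all probes the Pearson correlation of this pair was 0.982, the highest of the 15 pairs, and the median absolute log2 difference over measured probes was 0.154, against 0.275 for the muscle pair and 0.468 for the liver pair. Of 15753 measured probes, 0 were 2-fold higher and 430 were 2-fold lower on the MCSE liver array. The array labelled PBS adipose stood apart from every other array, with correlations between 0.307 and 0.517. Proteasome genes, used by every tissue, were dim on it. They had a median log2 intensity of 8.87, near the median of all its probes (8.95), where the other 5 arrays gave 12.63 to 13.09, and 3 of 29 proteasome genes reached its upper quartile against 27 or 28 elsewhere. Oxidative phosphorylation genes were less dim, with a median of 10.82 (against 13.68 to 14.55) and 22 of 33 in the upper quartile (against 31 to 33). White adipocyte genes had a median of 9.67 on this array, below the 12.35 of the PBS muscle array. Some contractile genes of slow and cardiac muscle were bright on it, among them Myl2 at 15.15 and Actc1 at 14.79. For these reasons "liver" and "adipose" below name the label of an array, and not a tissue identified by its transcripts.

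**Figure D1:**
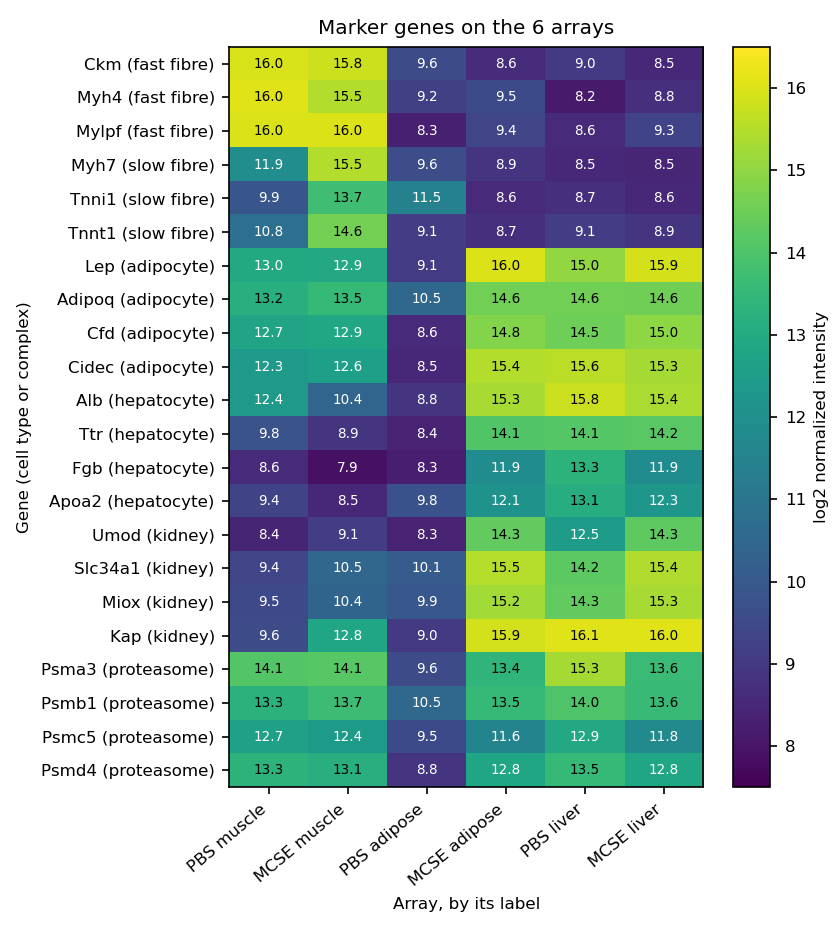
Log2 normalized intensity (colour, and number in each cell) of 22 marker genes in rows, on the 6 arrays in columns, with the cell type or complex of each gene in brackets and 1 array per column. Fast-fibre genes such as Ckm mark both muscle arrays (15.96 and 15.83). Lep, Alb and Umod are bright together on both liver arrays and the MCSE adipose array, and proteasome genes are dim on the PBS adipose array.

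Tissues were then compared by label. With limma, on the PBS and MCSE array of each tissue as the 2 samples of a group, 50 of 13862 genes differed between muscle and liver and 49 between muscle and adipose at an adjusted p under 0.05 and at least 2-fold. All were higher in muscle, and 43 were shared by the 2 comparisons, which used the same muscle arrays and the same estimate of the spread. The genes that passed included 11 of the 20 fast-fibre genes tested in each comparison. The single direction depended on the adipose arrays. With either 1 of those left out, more genes passed as lower than as higher in muscle. Ckm was 7.11 ± 0.57 (SE) higher in muscle than in liver on the log2 scale, with an adjusted p from limma of 0.0238, and Atp2a1, the calcium pump of fast fibres, was 6.87 ± 0.52 higher with the same adjusted p. No gene passed between adipose and liver (0 of 13862 with limma, 226 at an unadjusted p under 0.05). The fitted difference of Alb between adipose and liver was -3.50 ± 1.98 (SE) and that of Lep -2.95 ± 2.05, both with an adjusted p of 0.719. Because all 6 arrays shared 1 estimate of the spread, the gap between the 2 adipose arrays set much of it. Without either of them the muscle and liver comparison gave 2925 genes, and without the PBS muscle, MCSE muscle, PBS liver or MCSE liver array it gave 0. Muscle and adipose gave 1738 genes without the PBS adipose array, 7051 without the MCSE adipose array and 0 without any of the other 4. Adipose and liver gave 8252 without the MCSE adipose array and 0 without any of the other 5.

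In muscle, 418 of 10711 measured genes were at least 2-fold higher with MCSE and 201 were at least 2-fold lower. Over all measured genes the difference had an SD of 0.552, close to the SD per probe of 0.519. Much of this spread could thus be probe error or differences between transcripts, and the counts can hold many such genes. Genes of slow-twitch fibres, chemokines and the heat shock gene Hspa1b were among the steepest of the higher genes. All 11 slow-fibre genes lay above 0, with a median of 1.21 ± 0.73 (bootstrap SD over members), higher than in 100% of 10000 random lists matched on expression. The slow troponins Tnni1 and Tnnt1 were both 3.84 higher, Myh7, the slow myosin heavy chain, 3.54 and Tpm3, slow tropomyosin, 2.62. A second, dim probe for Myh7 gave 0.16. Fast-fibre genes had a median of -0.04, and 0 of 19 passed 2-fold. Many of them lay near the top of the intensity scale on both arrays, such as Mylpf at 16.01, so a rise could hardly show.

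Inflammatory genes were the pathway list that stood furthest from random lists in muscle. Of 22 measured cytokine and NF-kB target genes, 9 were 2-fold higher with MCSE and 0 were lower, with a median of 0.68 ± 0.33 (percentile 100). Ccl2, which attracts monocytes, was 2.68 higher, Cxcl1, which attracts neutrophils, 2.59, and Ccl7 2.27. Socs3, an inhibitor of cytokine and insulin receptor signalling, was 1.97 higher. Tnf (-0.06) and Il1b (0.18) differed by less than the SD per probe. Macrophage genes had a median of 0.21 with 0 of 18 past 2-fold (percentile 99.0), and neutrophil genes 0.35 with 1 of 8 (98.9). Several other lists lay above the central range as well, although 3 of the fixed lists in place of 9 did so with an upper quartile filter on dim probes. White adipocyte genes had a median of 0.24 (98.1), brown adipocyte genes 0.36 (97.9), smooth muscle genes 0.37 (98.3), extracellular matrix genes 0.20 (99.4) and acute phase genes 0.24 (98.2). The kidney genes had a median of 0.50 (percentile 100), with 3 of 17 genes 2-fold higher and 0 lower. Kap, an abundant kidney transcript, was 3.20 higher, more than Ccl2, Cxcl1, Ccl7 or Socs3. Whether kidney RNA contributed to the differences of other genes on the muscle pair was not tested.

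Among the stress and early response genes in muscle, Atf3, a transcription factor induced by many stresses, was 3.40 higher and Hspa1b, an inducible Hsp70, 5.01 higher. Of 14 heat shock genes, 4 were 2-fold higher, including Hsp90aa1 (1.5), Bag3 (1.31) and Dnajb1 (1.06), although the list as a whole stayed within the range of random lists (median 0.14, percentile 91.1). Of 25 immediate early genes, 5 were higher, such as Myc (1.24), Cyr61 (1.12) and Fos (1.11), and Egr1 alone was lower (-1.92). The median of this list was 0.08 (87.0). The circadian clock list was the only 1 of the 40 fixed lists measured in muscle that lay below the central range of random lists, at -0.35 ± 0.08 (percentile 0.3), with Dbp, an output gene of the clock, at -1.37. Glucocorticoid and fasting genes lay within the central range (median -0.10, percentile 31.2), with 0 of 19 members 2-fold higher and 2 lower, Ddit4, an inhibitor of mTORC1, at -1.48 and Errfi1 at -1.15.

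Genes of insulin action in muscle differed little as a group. The 47 measured insulin signalling genes had a median of -0.12 ± 0.06 (percentile 16.7). Socs3 was the only member 2-fold higher, and Cbl (-1.72) and Pik3r1 (-1.06), the regulatory subunit of PI 3-kinase, were 2-fold lower. Insr, the insulin receptor, was at -0.72. Akt2 (0.02) and Slc2a4, which encodes the GLUT4 glucose transporter (-0.17), lay within the SD per probe. Pdk4, which restrains glucose oxidation and is lowered by insulin, was at -0.80, Ucp3 at -0.89, Ppargc1a at -0.65 and Hk2 at -0.47. Irs1 was not above the filter, and Irs2 and Foxo1 were not found under these symbols. Eno3, the muscle enolase, was 1.55 higher, Ugp2, which makes the glucose donor for glycogen, 1.28 higher, and Adfp (now Plin2), which coats lipid droplets, 1.22 higher. The oxidative phosphorylation list lay within the central range (median 0.05, percentile 89.7), while Ndufb9 (-3.0), Atp5b (-2.97), Cox5a (-1.65) and Ndufb3 (-1.26) were lower and Atp5a1 (1.09) was higher.

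Several of the steepest muscle differences among genes above the lower quartile on both arrays rested on 1 probe. Outside that limit, Smyd1 was at -7.23 in muscle and 2.56 on the liver arrays. The predicted gene 1700037C18Rik was 6.93 higher on its bright probe and -0.08 on its other probe. Kctd20 (-4.04), Dtna (-3.76), Cobl (-3.26) and Dll4 (-2.80) were lower on the brightest probe, while their other probes differed by 0.62 or less in size. The other probes of 1700037C18Rik, Cobl and Dll4 lay below the median of all probes on both arrays, where a difference could hardly show. For 47 genes with 2 measured probes, the brighter probe was 2-fold higher. The second probe of these genes lay above 0 in 26, close to an even split, and was 1.5-fold higher in 9. For 33 genes lower on the brighter probe, the second probe lay below 0 in 25. Eno3 and Errfi1 differed by 0.05 and 0.01 on their second, dimmer probes. Second probes of Myc and Cyr61 gave 0.28 and 0.75 in muscle. The correlation between the 2 probes of a gene was 0.141 across 1504 genes, which are not independent replicates.

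**Figure D2:**
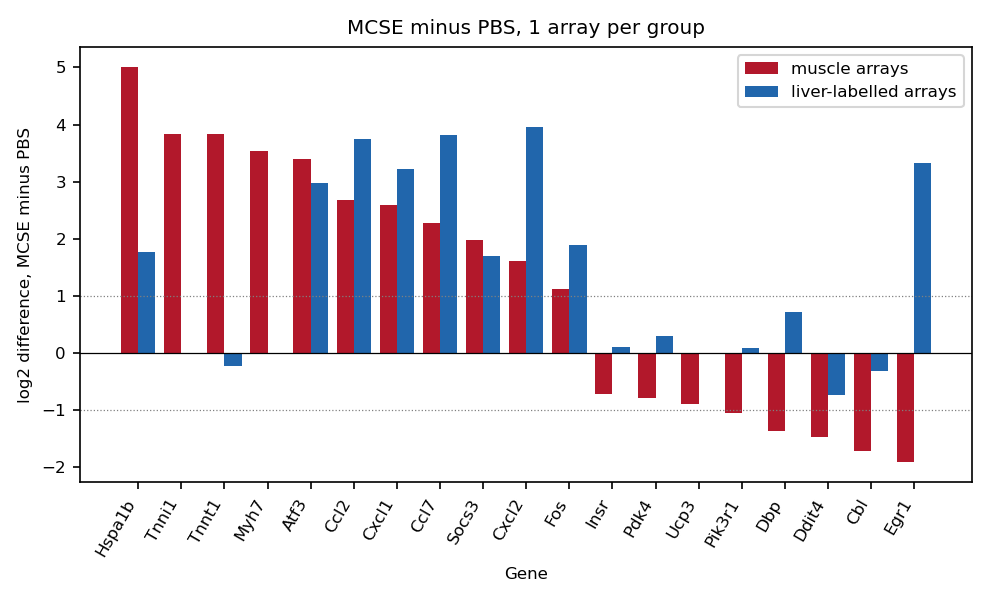
Log2 difference MCSE minus PBS (vertical axis) of 19 genes chosen from those named in the text after their values were seen, on the muscle arrays (red) and the arrays labelled liver (blue), 1 array per group and so without error bars. Dotted lines mark 2-fold, and a bar is missing where a gene was below the filter on dim probes. Ccl2, Cxcl1, Ccl7, Atf3 and Socs3 lay above the upper line on both pairs, and Egr1 lay at -1.92 in muscle and 3.33 on the liver arrays.

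On the arrays labelled liver, 938 of 11342 measured genes were at least 2-fold higher with MCSE and 682 at least 2-fold lower. Immediate early genes and chemokines were higher, as were the kidney genes. Of 25 immediate early genes, 14 were 2-fold higher and 0 lower, with a median of 1.38 ± 0.61 (percentile 100). Egr1, a zinc finger factor induced within minutes of stimulation, was 3.33 higher, Gadd45b 3.16, Nr4a2 3.12 and Myc 3.11. Of 21 inflammatory genes, 12 were 2-fold higher and 1 was lower, with a median of 1.23 ± 0.48 (percentile 100). Cxcl2 was 3.96 higher, Ccl7 3.81, Ccl2 3.74 and Cxcl1 3.21, whereas Lcn2 was at -1.73. Macrophage genes had a median of -0.22 (percentile 13.1). The kidney list had a median of 1.03 ± 0.16, with 14 of 27 genes 2-fold higher and 0 lower.

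Gluconeogenic and insulin-suppressed genes had a median of 0.61 ± 0.20 on the liver arrays (percentile 99.9), with 4 of 15 genes 2-fold higher and 1, Gpt1 (-1.0), lower. Ppargc1a, a coactivator of gluconeogenesis, was 1.74 higher, G6pc, the last enzyme of glucose release, 1.52 and Slc37a4, its substrate transporter, 1.32. On the PBS liver array Ppargc1a lay at 8.96, near the median of all probes (8.95). Pck1 differed by 0.21, and Srebf1, a lipogenic factor that insulin induces, by -0.14. Kidney, whose marker genes were also higher, expresses G6pc and Pck1 as well. Insulin signalling genes had a median of 0.09 (percentile 80.2), with Pik3cd (2.10), Socs3 (1.70), Grb14 (1.52), Cblb (1.30) and Sos1 (1.05) 2-fold higher and Flot1 (-1.10) and Eif4ebp1 (-1.04) 2-fold lower. Insr was at 0.10, Akt2 at -0.65 and Slc2a4 at -0.64.

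Clock genes on the liver arrays had a median of 0.56 ± 0.25 (percentile 99.7). Per3 was 2.71 higher, Bhlhb2 (now Bhlhe40) 1.64, Clock 1.32 and Nr1d1 1.04. Smaller shifts beyond the central range were those of lipolysis (0.42, percentile 97.8), bile acid and lipoprotein metabolism (0.34, 97.9), white adipocyte genes (0.36, 98.7) and oxidative phosphorylation (0.20, 98.4). Cholesterol synthesis genes had a lower median (-0.45 ± 0.25, percentile 1.2). Of 18 members, 1 was 2-fold lower, Nsdhl at -1.42, and 7 lay above 0. Slow-fibre genes, many of them shared with heart, were lower too (-1.24 ± 0.27, percentile 0.0), with Myl3 at -2.89. Outside that list, Mb, the oxygen store of muscle, lay at -4.14 and Actc1, cardiac actin, at -2.77. Pancreas genes (-0.71, percentile 0.5) and lymphocyte genes (-0.55, 1.1) were also below the central range, the lymphocyte median being 0.03 without the filter on dim probes. Hepatocyte genes had a median of -0.06.

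Many of the higher genes on the liver pair were dim on the PBS liver array and bright on 4 of the other arrays. Of the 938 genes, 403 (43.0%) lay at least 2-fold lower on the PBS liver array than on both muscle arrays, the MCSE adipose array and the MCSE liver array, and without them 535 were left. On the PBS adipose array, which was left out of this comparison, 130 of the 403 were at least 2-fold brighter than on the PBS liver array. Among genes above the lower quartile on both arrays, the 4 steepest differences were of this kind, those of Usp27x (4.67), Styx (4.35), Gpr4 (4.32) and Jmjd4 (4.21). Ccl2, Ccl7 and Cxcl2 were not, with log2 intensities of 8.85, 7.84 and 7.96 on the PBS muscle array. Ppargc1a of the gluconeogenic list was of this kind, at 8.96 on the PBS liver array and 10.53 to 11.71 on the 4 brighter arrays. Cd69 had the steepest negative difference (-4.90) among genes above the lower quartile on both arrays.

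Other probes of a gene often differed from its brightest probe on the liver pair as well. The second probe of Spred2 (-2.45) gave -0.02. Those of Cd69 and Nr4a2 gave 0.02 and -0.05, but lay below the median of all probes on both arrays, where a difference could hardly show. Clock, at 1.32 on its brightest probe, gave -0.16 and -0.08 on the others, and Per3 0.45. Cblb gave -0.51 and Nsdhl 0.54 (a dim probe) and -0.09, in each case with the opposite sign on at least 1 probe, while Ppargc1a gave 0.56 and Myc 0.55. Pck1 gave -0.40 on its second probe. On the liver arrays that probe was the brighter 1, at 15.74 (PBS) and 15.34 (MCSE) against 14.93 and 15.14. Among 132 genes with 2 measured probes whose brighter probe was 2-fold higher, the second probe lay above 0 in 82 and was 1.5-fold higher in 32. For 95 genes lower on the brighter probe, the second lay below 0 in 58 and was 1.5-fold lower in 25.

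**Figure D3:**
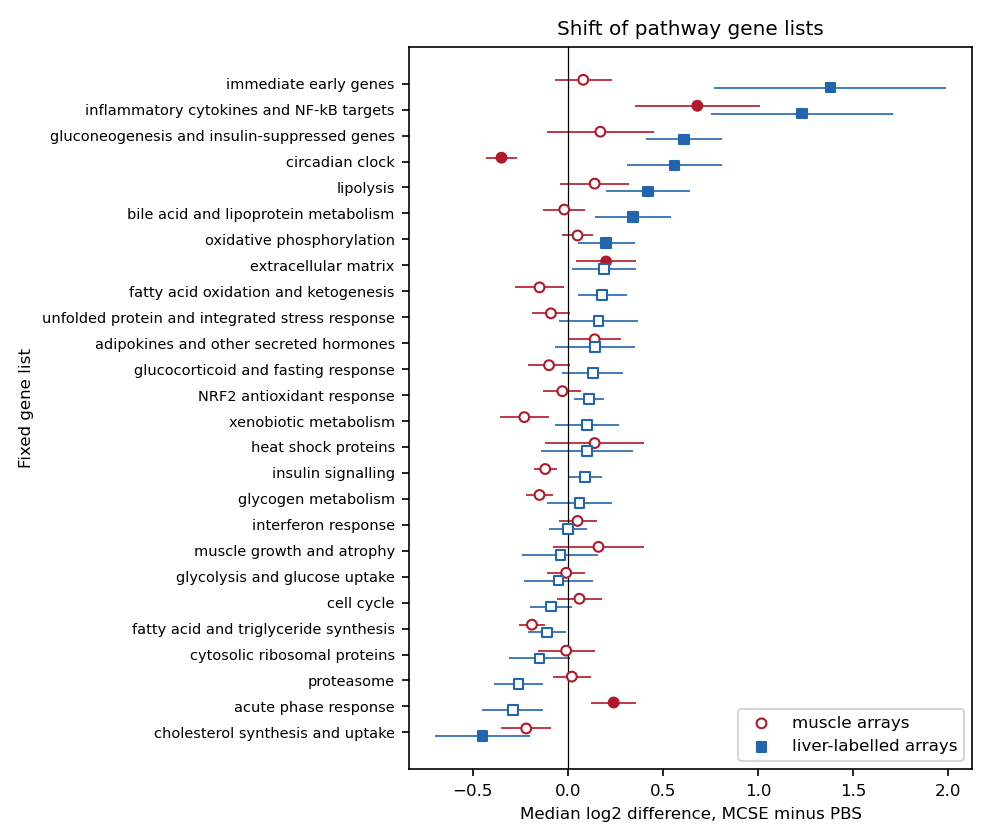
Median log2 difference MCSE minus PBS (horizontal axis) of the measured members of 26 fixed pathway lists, on the muscle arrays (red circles) and the arrays labelled liver (blue squares), with error bars of 1 bootstrap SD over members. Filled symbols lie outside the central 95% of 10000 random lists. Inflammatory genes are filled on the positive side for both pairs (0.68 and 1.23), and the circadian clock lies at -0.35 in muscle and 0.56 on the liver arrays.

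Differences on the adipose pair covered most of the array. Of 13133 measured genes, 4930 were 2-fold higher and 4508 2-fold lower on the MCSE array, together 71.9%. Proteasome genes had a median of 3.60, oxidative phosphorylation genes 3.22 and white adipocyte genes 4.08, each in the direction given by the dim signals on the PBS adipose array. Lep was 6.97 higher, Fasn, the fatty acid synthase, 5.81 and Adipoq 4.08. Insr, the insulin receptor, was at -3.50 and Slc2a4 at -0.12. Akt2 was 1.27 higher on its brightest probe and at -0.98 and 0.40 on its other probes, and Irs1 was below the filter. Anxa1 (7.41) and Car3 (7.37) were the steepest among genes above the lower quartile on both arrays, and Stx6 (-6.24) and Clec4e (-5.87) the lowest. With the PBS array apart from all others and the MCSE array matching the MCSE liver array, these values compare 2 arrays whose tissue was not identified. Retn was not found under this symbol.

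The last comparison asked whether MCSE went with the same differences in different tissues. Muscle and liver, which shared no array, had a correlation of 0.268 (Pearson) and 0.281 (Spearman) across 9578 genes, which are not independent replicates. Of these genes, 101 were 2-fold higher in both, where independent lists would share 23.8, and 17 were lower in both, against 10.1. Another 26 went opposite ways, against 31.3. Ccl2, Ccl7, Cxcl1, Cxcl2, Socs3, Atf3, Fos, Myc (on its brightest probe only) and Hspa1b were among those higher in both. So was the kidney gene Slc34a1, and the kidney list was higher on both pairs (medians 0.50 and 1.03). The numbers for independent lists take no account of composition or handling that both MCSE arrays may share. A response to MCSE was therefore not separated from these. Muscle and adipose had a correlation of 0.009, and adipose and liver 0.379, with nearly identical MCSE arrays in the latter pair.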

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

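The tests of explanations in this part were all chosen after the results were seen. Between muscle and the arrays labelled liver, 2 fixed lists lay outside the central range of random lists on opposite sides, and 4 of the genes named by the rule fixed beforehand passed 2-fold in opposite directions, among 26 of all 9578 genes measured on both pairs. With 1 array per group these differences between tissues were not tested. The circadian clock list had a median of -0.35 in muscle and 0.56 on the liver arrays. The slow-fibre list had 1.21 in muscle and -1.24 on the liver arrays, where 7 members were measured, most of them shared with heart, such as Myl2, Myl3 and Tnnc1. Egr1 lay at -1.92 in muscle and 3.33 on the liver arrays. Hsp90aa1 lay at 1.5 and -1.03. Myl3 lay at 1.21 and -2.89, and Dll4 at -2.80 and 1.30, although the second, dim Dll4 probe gave 0.17 in muscle. The adipose pair was left out of this comparison because its PBS array stood apart from all others.

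For the higher slow-fibre genes on the MCSE muscle array, a larger share of heart muscle is argued against by heart genes. Their median difference was -0.22 ± 0.30 (bootstrap SD, 9 measured genes, 3 above 0). Their median log2 intensity, over 13 genes, was 10.97 on the PBS muscle array and 10.86 on the MCSE muscle array. Heart muscle on both arrays was therefore not excluded. Myh6 was at -1.15 and Tnnt2 at -0.84, whereas Myl7, an atrial gene, was at 1.79. A larger share of slow muscle in the MCSE sample and a fibre-type response to MCSE cannot be told apart. That 11 of 11 slow-fibre genes lay above 0 is the pattern itself and favours neither, and Ppargc1a, a coactivator of the slow programme, lay at -0.65 but could have returned to its level by 4 h.

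The higher chemokine and immediate early genes on the MCSE liver array could have come with other cells. More macrophages are argued against by the macrophage genes as a set, whose median was -0.22 ± 0.15. Their members went both ways, with 7 of 22 above 0, so a change in the kind of macrophage is not excluded. Neutrophil genes had a median of -0.22 ± 0.41 and endothelial genes 0.01 ± 0.16. If the kidney RNA itself was alike in both samples, which was not measured, a higher share of it would raise no gene by more than kidney genes. The steepest of these was Slc22a12 at 2.17, and 11 of 46 measured members of both lists exceeded it by more than the SD per probe. Those 11 were the steepest members, so a higher share of kidney RNA stays open for the lists as a whole. Handling at dissection and a response to MCSE cannot be told apart with 1 array per group, as handling can differ between tissues, and Egr1 lay at -1.92 on the muscle arrays while Atf3 and Ccl2 were higher on both pairs.

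Probes without a gene symbol, which entered no count of genes, also differed. On the muscle pair 219 such probes were 2-fold higher with MCSE and 72 lower, on the adipose pair 1195 and 2632, and on the liver pair 353 and 318.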

How the results depend on the processing

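Alternatives that exchanged the MCSE liver array or left out genes dim on the PBS liver array were chosen after the data were seen; the others were planned. Pairing by replicate number was not possible, because each group held replicate 1 only. The tissue label pairs each PBS array with an MCSE array. Treatment as a term of the tissue fit gave 34, 0 and 37 genes (muscle and liver, adipose and liver, muscle and adipose). A fit of MCSE with tissue as a block would have 2 residual degrees of freedom and was not run, since the tissues are not replicates of each other. Quantile normalization moved almost nothing, since the arrays already shared 1 distribution, and so is no check of the scaling. Of the alternatives for lists, 299 of 320 in muscle and 298 of 316 on the liver arrays stayed within the error of the median, and for named genes 456 of 469 and 616 of 630 stayed within the SD per probe. Most of these alternatives could move a named gene only slightly, since the filters leave its difference unchanged. The shares for named genes are therefore no check of single genes. For lists, quantile normalization and centring, on medians of -0.051 in muscle and -0.015 on the liver arrays, could hardly move a value. The error allowed was each list's own bootstrap SD, such as 0.73 for slow-fibre genes in muscle. The shares for lists are therefore a weak check as well. Reversals were the lymphocyte list on the liver arrays (0.03 without a filter on dim probes) and Aqp7 on the adipose pair (0.06 as the mean over all probes), whose 3 probes went different ways. At 1.5-fold the higher and lower genes numbered 1016 and 847 in muscle and 2275 and 2093 on the liver arrays, which follows from the lower threshold. At 3 running SDs 108 muscle genes were lower, 154 and 37 liver genes were higher and lower, and 1 and 0 genes on the adipose pair, where the SD itself was wide. Exchanging MCSE liver for MCSE adipose gave 1433 higher genes and a muscle and liver correlation of 0.225, and leaving out the genes dim on PBS liver gave 535 and 0.218. Every gene left out was by definition 2-fold higher on the liver pair, so the lower count was fixed in advance. The correlation without them rests on genes selected by their liver difference, so neither value is a check. The upper quartile filter left 3 muscle lists above the central range in place of 9, with fewer members measured, and no filter left 2 below it. That filter gave an SD per probe of 0.611 in muscle and 2.005 for adipose, and correlations of 0.402 (adipose and liver) and -0.02 (muscle and adipose). No filter gave SDs of 0.442 for muscle, 1.522 for adipose and 0.546 for liver. The cause of these shifts was not tested. With 1 array left out, the lone array being assumed to vary like the others, limma gave 0 to 2925 genes between muscle and liver, 0 to 8252 between adipose and liver, the highest without MCSE adipose, and 0 to 7051 between muscle and adipose. In that order the counts were 2925, 0 and 1738 without PBS adipose, 2925, 8252 and 7051 without MCSE adipose, and without any muscle or liver array 0 in each comparison. Signal over background was not used here, so dim genes carry an unknown share of background.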

Other observations

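All tests of explanations in this part were chosen after the results were seen. Some further lists lay within the central range of random lists on the liver arrays but held members past 2-fold. Of 20 NRF2 antioxidant genes, 2 were 2-fold higher, Gclc, which starts glutathione synthesis (1.77), and Osgin1 (1.51), with a list median of 0.11 (percentile 79.7). Glucocorticoid and fasting genes (percentile 83.3) included Dusp1 (2.11), Klf15 (1.65) and Sgk1 (1.28) on the higher side and the muscle atrophy ligase Fbxo32 (-1.57) on the lower side. Of the bile acid and lipoprotein genes, which lay above the central range, Apoa5 was 1.70 higher and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -1.08. Among 24 fatty acid oxidation genes (percentile 94.6), Acot2 (1.23) and Ehhadh (1.21), which PPARalpha induces, were higher, and Hadha (-2.25) and Acadl (-1.43) lower. Acute phase genes had a median of -0.29 (percentile 9.2), with Fgb at -1.45 and Itih3 at -1.26, while Socs3 was higher.

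In muscle, regulators of fibre growth went both ways. Csrp3, a stretch-sensor gene most abundant in slow fibres and heart, was 1.84 higher, Myh3, an embryonic myosin, 1.12 and Myf6 1.01, and Mef2c was at -1.37. Among NRF2 genes Srxn1 was 1.64 higher on its brightest probe and 1.26 and 0.39 on its other probes, and Txnrd1 was at -1.77. The matrix gene Col5a1 was 1.29 higher. Col5a2 was 1.20 higher on its brightest probe and at 0.41 and -0.07 on its other probes, and on the liver arrays at 1.18, 0.61 and 0.60.

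Marker genes departed from the tissue labels on 4 arrays. A fat-laden liver, which ob/ob mice have, was set against the kidney genes. On the PBS liver array these lay 2.37 ± 0.63 (median difference, bootstrap SD) above the PBS muscle array. That list was drawn up after kidney genes were seen bright on this array, so it is no independent test of a fat-laden liver. RNA of several organs on 1 array stays open. The white adipocyte, hepatocyte and kidney genes were all higher there, the lowest median difference being 1.54, but these lists are what raised the question and so favour nothing. A weak or failed hybridisation of the PBS adipose array also stays open, as 3 of 29 proteasome genes but 22 of 33 oxidative phosphorylation genes lay in its upper quartile. Where in the chain from dissection to the deposited table the labels and the transcripts parted was not tested.

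The 500 brightest probes of the PBS adipose array had a median percentile of 93.7 on the PBS muscle array and 85.9 on the MCSE liver array. With the MCSE adipose array in place of the MCSE liver array, differences from the PBS liver array correlated at 0.951 across 11206 genes with those of the liver pair, sharing that PBS array, and 844 genes were 2-fold higher in both.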
